A study of Mus musculus with 12 samples.

How the data were processed

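TuBo is a cell line cloned from a mammary carcinoma of a mouse that carried the activated rat Erbb2 oncogene. Expression was measured in TuBo cells grown attached to plastic and in TuBo mammospheres, the floating spheres that some epithelial cells form when they cannot attach, at passages P1, P2 and P3. Per the labels, attached cells grew in medium with 20% serum. Mammospheres were given insulin at 5 µg/ml, the growth factors bFGF and EGF at 20 ng/ml each, and albumin at 0.4%, and were collected after 7 days. Sphere growth, growth without serum and these additions, which the labels name for mammospheres only, therefore changed together in each comparison with adherent cells. Each of the 4 groups had 3 arrays, 12 in all, each made from 500 ng of total RNA on Illumina mouse whole-genome beadchips. The series' design text describes the replicates as independent experiments, and the labels number them 1 to 3. Groups and numbers were taken from the labels alone. Whether a number marks arrays of 1 shared experiment was checked by the correlation of deviations from the group means. For P2 and P3 it was over 0.1 in 3 of 3 pairs (0.298 to 0.405), so the numbers in the labels were taken to pair these 2 groups. The fit has no block. For P3 against P2 a fit over all 12 arrays with the experiment number as a block is given beside it. For each other pair of groups at least 1 of 3 pairs was not over 0.1.

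The deposited values of each array were summarized probe intensities on a linear scale from BeadStudio 3, per the submitters' processing notes. They came without a detection p, a slide or a scan date, and whether background had been subtracted is not given in the sources used here. The lowest value on each array lay between 55.7 and 89.5, so no offset was needed. The series table deposited by the authors holds log2 values of the same arrays, with medians between 6.93 and 6.94. Their correlation with the log2 intensities was between 0.9986 and 0.9999 over the 45281 probes. The normalization behind that table is not given in the sources used here, and it served as an alternative. No 2 arrays had identical values.

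The intensities were log2 transformed and quantile normalized with limma 3.58.1 in R 4.3.3, without background correction. This was the setting fixed before the data were examined for values that come with no detection p. Probes whose mean over the 12 arrays was at or below the 50th percentile were left out, which kept 22640 of 45281 probes. The platform annotation gave 1 gene symbol for 34885 probes, several for 18 and none for 10378, and a RefSeq gene table changed 0 of the symbols. Of the probes kept, 3751 had no single symbol and were tested but not named. For gene lists and named genes, each of 12374 genes was represented by its kept probe with the highest mean. Where the mean of all kept probes ended the call of a named gene, or moved the fold change of a called one by over 1.5 times, that mean is given.

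Levels are normalized log2 intensities. The median over all probes was 6.93 and the highest value 15.99. Values close to 7 lie at the floor of the array, so that a fold change against such a level understates the difference. The number of arrays limits the precision of every value. No level of a probe is compared with that of another probe.

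A linear model with 1 mean per group was fitted over all 12 arrays with lmFit and eBayes of limma. The contrasts were each passage against adherent cells, the mean of the 3 passages against adherent cells, and the passages against each other, 7 in all, plus limma's moderated F for any difference among passages. A probe was called at a Benjamini-Hochberg adjusted p of at most 0.05 over the probes kept, with an absolute log2 fold change of at least 1. These are the thresholds stated in the series' design text. Unless said otherwise, each adjusted p of a gene comes from this fit and each fold change is log2, mammospheres minus adherent cells. A gene named from a list is said to have risen or fallen at an adjusted p of at most 0.05 without the fold threshold. SE is the standard error from the fit, and SD is taken over the 3 arrays of a group.

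The 29 gene lists were written down before the data were examined, and 1 listed gene, H2-L, was not matched. Each list was tested with camera of limma at a preset correlation between genes of 0.01. It was tested again with a correlation estimated from the data, and with fry, which asks whether the genes of a list move on balance in 1 direction. Values of p were adjusted over the lists. The named genes follow a rule also fixed beforehand. They were the 12 largest mean rises and the 12 largest mean falls among genes called in each passage in 1 direction, and up to 5 rises and 5 falls called between passages. For each list they were the 2 largest rises and falls at an adjusted p of at most 0.05 or, failing these, the 2 smallest p. A fixed set of stem cell, keratin, Erbb2 and follow-up genes was always included.

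The procedure was tested on simulated arrays with the residual spread of each probe, pooled over the groups and so equal in all 4. For the mean of 3 passages against adherent cells it recovered 88.1% of probes changed by 1.5 log2, 100% at 2 and 100% at 3, and it called 1 of 22440 unchanged probes. For P3 against P1 it recovered 85.1%, 97.0% and 100%, and called 4 of 22440. The changed probes were drawn at random from all probes kept. Recovery is therefore an average over them, and can be lower for probes with a large spread. The 3 comparisons with adherent cells share their control arrays, and their overlaps are therefore set beside 100 simulated draws of unchanged groups. These draws used the spread of each group apart, and gave 17.5 to 17.8 shared calls per pair of comparisons. The counts of unchanged probes called under the pooled spread may therefore be too low for these arrays. The alternatives tried were median scaling, the deposited log2 values, no filter, a further filter on the interquartile range at 0.5, a block for the experiment number, array weights, an intensity trend with a robust prior, only the arrays compared, no fold threshold, the mean of all kept probes of a gene, and leaving out each array in turn. Chosen after seeing the data were normexp background correction with an offset of 50 and a filter at the 75th percentile. The background correction with detection p, the filters on detection p and a block for the slide could not be run on these values.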

Results

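Normalized log2 intensities were compared between adherent TuBo cells and TuBo mammospheres of passages P1, P2 and P3, with 3 arrays in each of the 4 groups. The comparison asks which transcripts differ between cells grown attached and cells grown as spheres, and whether successive passages of spheres differ from each other. Before normalization, the median intensity of an array lay between 99.4 and 150.5. After it, Pearson's r between arrays, across probes, ranged from 0.923 to 0.989.

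The adherent array of experiment 1 stood apart from the other 11 arrays. Its mean r with them was 0.926, while the lowest r among those 11 arrays was 0.958. Of the 24 genes of the matrix list 18 were at least 1 log2 higher on it than on the other 2 adherent arrays, and of the 22 mesenchymal genes 13. Sparc, a collagen-binding matrix protein, had a log2 intensity of 14.84 there and a mean of 6.89 on the other 11 arrays. Lox, a collagen cross-linking enzyme, had 14.97 against 6.74, the surface glycoprotein Thy1 13.34 against 6.86, and fibronectin, Fn1, 12.49 against 6.78. Car12, a membrane carbonic anhydrase, had 10.13 on this array and 13.19 on the other 11. The first principal component, with 35.3% of the variance, placed this array at -88.0 and the other 11 arrays between -12.9 and 15.0. These genes were chosen after their values were seen.

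**Figure D1:**
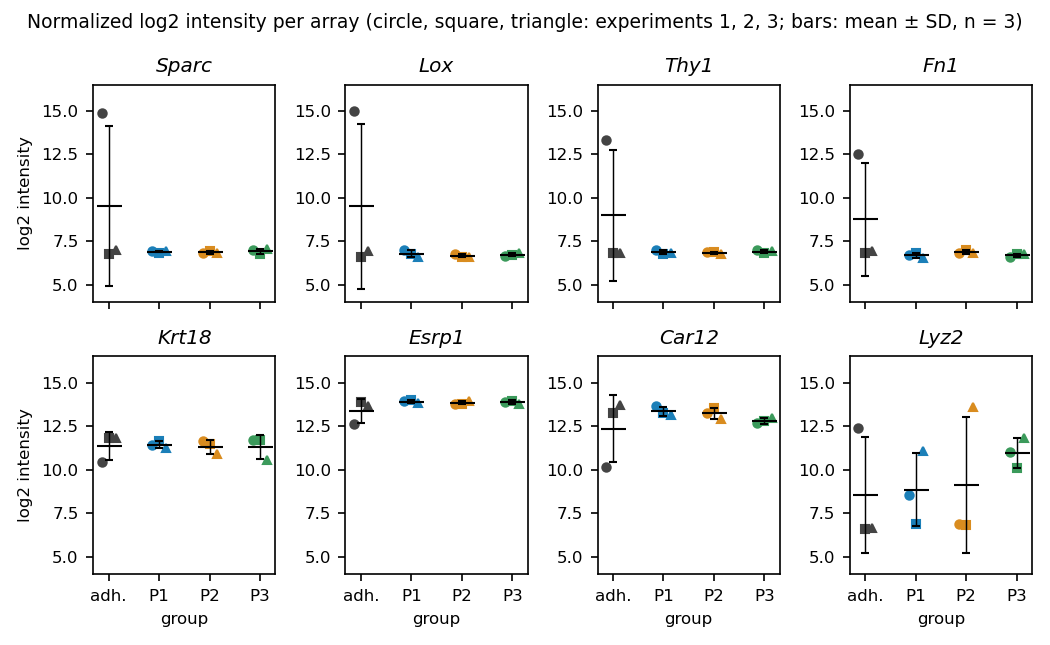
Normalized log2 intensity (vertical axis) per array of 8 genes in adherent cells (adh.) and mammospheres of passages P1, P2 and P3; symbols give the experiment and bars the mean ± SD, n = 3 arrays per group. Sparc, Lox, Thy1 and Fn1 are near 7 on the other 11 arrays and between 12.49 and 14.97 on the adherent array of experiment 1, and Lyz2 varies within groups.

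Of genes whose transcripts were called in each of the 3 passages, 24 were higher and 49 lower in mammospheres than in adherent cells. The largest mean rise was that of Klk14, a kallikrein-related serine protease, from 7.93 ± 0.67 in adherent cells (SD, n = 3) to 13.51 ± 0.77 in P1, 11.72 ± 0.34 in P2 and 12.62 ± 1.87 in P3. Its mean log2 fold change was 4.69 (SE 0.61, adjusted p = 0.00273), and another kallikrein, Klk10, rose by 3.02 (SE 0.41, adjusted p = 0.00317). The neutrophil-attracting chemokine Cxcl2 rose by 3.68 (SE 0.54, adjusted p = 0.00465) and Clca2, a regulator of chloride channels, by 2.54 (SE 0.30, adjusted p = 0.00138). The folate receptor Folr1 rose by 2.28, the whey acidic protein family member Wfdc18 by 2.21, Cdr2 by 2.15 and the heparan sulfate sulfotransferase Hs3st3a1 by 2.01. Smaller rises were those of the transporters Slc22a23 (1.72), Slc6a2 (1.68) and Slc12a2 (1.65), and of Rap1gap2 (1.60), a GTPase activator. Across these 12 genes the adjusted p ranged from 0.000431 to 0.00808, and each was higher on 9 of 9 mammosphere arrays than on every adherent array. A second kept probe of Rap1gap2, at 7.06 in adherent cells, had a fold change of 0, and that of Folr1 one of 0.56. With the mean of all kept probes of a gene in place of the brightest, the fold change was 0.80 for Rap1gap2, 1.42 for Folr1, 0.98 for Slc22a23 and 0.74 for Slc6a2. All 12 kept an adjusted p of at most 0.05 without each array in turn.

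Among genes called in each passage, the largest mean falls were those of Prss22, Ccn1 and Sdc3. Prss22, a serine protease, fell by 3.03 (SE 0.45, adjusted p = 0.00511). It stood at 13.75 ± 0.29 in adherent cells, 10.67 ± 1.09 in P1, 11.16 ± 0.93 in P2 and 10.33 ± 0.63 in P3 (SD, n = 3). Ccn1, a matrix-associated signalling protein, fell by 2.95 (SE 0.33, adjusted p = 0.00118). The heparan sulfate proteoglycan Sdc3 fell by 2.83, to between 7.32 and 7.62 in the 3 passages, near the floor, and the collagen prolyl hydroxylase subunit P4ha2 had a fold change of -2.81, the mucin Muc1 -2.60 and Ndrg1, a gene induced in hypoxia, -2.27. Further falls were those of the endosomal GTPase Rab7b, with a fold change of -2.25, Pdlim2 (-2.20), the non-coding RNA Snhg18 (-2.19), and the cyclic nucleotide phosphodiesterase Pde2a (-2.17). The ERK phosphatase Dusp5 had -2.12 and connexin 43, Gja1, -2.11. The smallest adjusted p were those of Pde2a (2.74e-05) and Rab7b (3.69e-05), and the highest that of Snhg18 (0.00982). Each was lower on 9 of 9 mammosphere arrays than on every adherent array, and kept an adjusted p of at most 0.05 without each array in turn. Without the adherent array of experiment 1, falls were smaller for Ccn1 (-2.51), Sdc3 (-1.98), P4ha2 (-2.02) and Snhg18 (-1.47). They were also smaller for Rab7b (-2.17), Pdlim2 (-1.91), Pde2a (-2.10) and Dusp5 (-1.98). Larger falls were then those of Prss22 (-3.19), Muc1 (-2.87), Ndrg1 (-2.42) and Gja1 (-2.33). The order of the falls therefore depends on that array. With median scaling in place of quantile normalization, the adjusted p rose to 0.0500 for Prss22, 0.0666 for Gja1 and 0.0618 for Snhg18, just above the threshold before rounding.

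**Figure D2:**
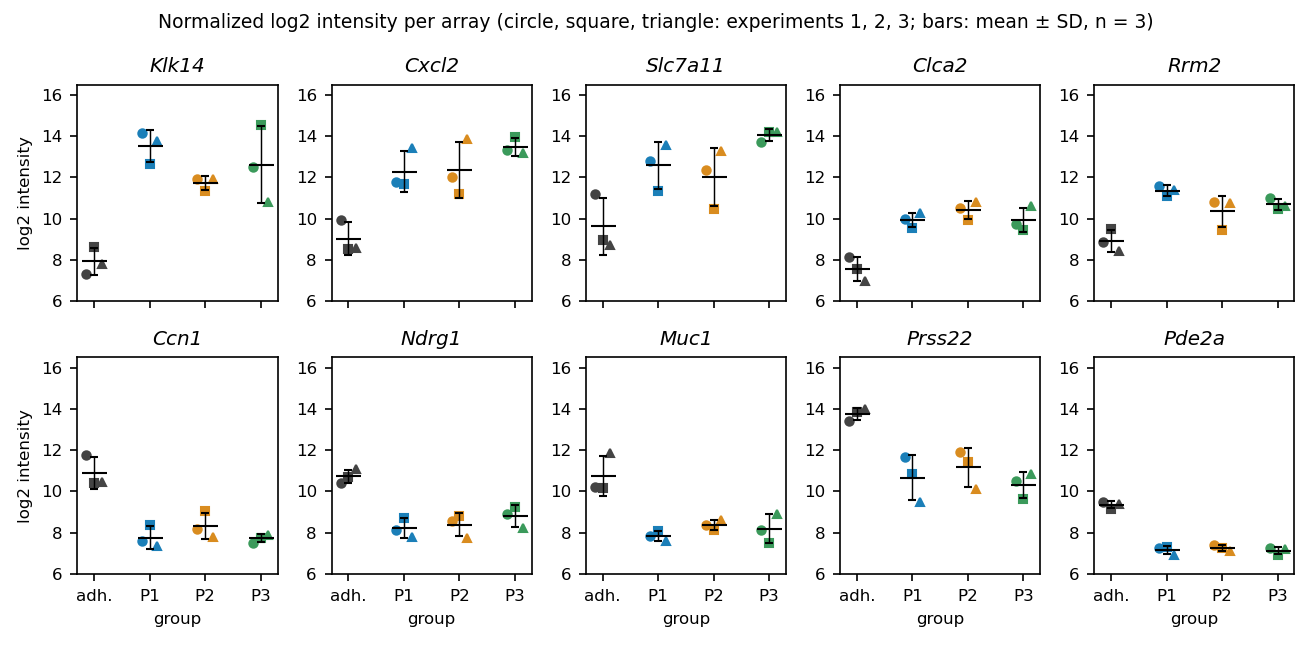
Normalized log2 intensity (vertical axis) per array of 10 genes in adherent cells (adh.) and mammospheres of passages P1, P2 and P3; symbols give the experiment and bars the mean ± SD, n = 3 arrays per group. Klk14, Cxcl2 and Clca2 are higher, and Ccn1, Ndrg1, Muc1, Prss22 and Pde2a lower, on 9 of 9 mammosphere arrays than on every adherent array.

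Of the 29 gene lists, 7 were higher and 8 lower in mammospheres by camera with the preset correlation, for the mean of 3 passages. With an estimated correlation 0 of the 29 lists passed, the smallest adjusted p being 0.329, while fry gave 7. Those by fry were the NRF2, hypoxia, SRF and YAP, MHC and oxidative phosphorylation lists (adjusted p = 0.018 each). The p53 targets and the follow-up genes of later work also passed it (adjusted p = 0.041 each). No other list passed fry, the DNA replication list having 0.0744 and the cholesterol list 0.0739. Camera gave 9 lists without the adherent array of experiment 1, 8 of them among the 15, and with an estimated correlation 0 passed there (smallest adjusted p = 0.331). The lists are described in that order, and n is 3 arrays per group throughout.

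The NRF2 and glutathione list, genes of antioxidant defence, was higher, with a mean fold change of 0.51 over 27 genes (adjusted p = 0.000731, and adjusted p = 0.329 with an estimated correlation). Of its genes 8 rose and 0 fell, or 11 and 0 adjusted over the list alone. The list mean was 9.65 ± 0.14 in adherent cells, 10.02 ± 0.19 in P1, 9.93 ± 0.21 in P2 and 10.52 ± 0.01 in P3 (SD), and the list did not pass in P2 (adjusted p = 0.0206 in P1, 0.0668 in P2 and 2.80e-07 in P3). These were 0.382, 0.523 and 0.141 as adjusted p with an estimated correlation. Slc7a11, the cystine transporter subunit that feeds glutathione synthesis, had the largest rise, 3.25 (SE 0.65, adjusted p = 0.019), and stood above every adherent array on 8 of 9 mammosphere arrays. Its adjusted p was 0.0685 without the adherent array of experiment 2 and 0.0923 without that of experiment 3. Its other kept probe, near the floor at 7.10 in adherent cells, had -0.02, and the mean of both 1.61. The glutathione transferase Gsta3 rose by 2.34 (SE 0.41, adjusted p = 0.0104).

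The DNA replication list was higher by 0.52 over 26 genes (adjusted p = 5.68e-06, and adjusted p = 0.469 with an estimated correlation), with 2 genes risen and 0 fallen, or 7 and 0 adjusted over the list alone. Its mean was 8.93 ± 0.29 in adherent cells, 9.91 ± 0.18 in P1, 9.12 ± 0.45 in P2 and 9.32 ± 0.15 in P3 (SD). The mean fold change was 0.98 in P1 (adjusted p = 1.76e-14), 0.19 in P2 (adjusted p = 0.144) and 0.39 in P3 (adjusted p = 0.00259), and with an estimated correlation the adjusted p was 0.382, 0.723 and 0.678. The low P2 value hangs on the array of experiment 2, where the list stood at 8.60 against 9.36 and 9.40 on the other P2 arrays. Rrm2, a ribonucleotide reductase subunit, rose by 1.86 (SE 0.29, adjusted p = 0.00642), and the flap endonuclease Fen1 by 1.20 (adjusted p = 0.013, and 0.0661 without the adherent array of experiment 3). The oxidative phosphorylation list was higher by 0.27 over 26 genes (adjusted p = 0.0012, and adjusted p = 0.465 with an estimated correlation), with 5 genes risen and 0 fallen, or 10 and 0 adjusted over the list alone. Its list mean was higher on 9 of 9 mammosphere arrays than on every adherent array. Cytochrome c, Cycs, rose by 1.03 (SE 0.17, adjusted p = 0.009, and 0.132 with median scaling), and by 0.38 as the mean of its kept probes.

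The p53 target list was higher by 0.25 over 20 genes (adjusted p = 0.0122, and adjusted p = 0.469 with an estimated correlation), and the endoplasmic reticulum chaperone list by 0.23 over 18 genes (adjusted p = 0.0463, and adjusted p = 0.469 with an estimated correlation). In P1, P2 and P3 the mean fold change was -0.04 (adjusted p = 0.994), 0.45 (adjusted p = 0.000128) and 0.33 (adjusted p = 0.00431) for the p53 targets. For the chaperones it was 0.25 (adjusted p = 0.0575), 0.32 (adjusted p = 0.00677) and 0.12 (adjusted p = 0.414). With an estimated correlation neither list passed in any passage (smallest adjusted p = 0.437). Each list had 1 gene risen and 0 fallen for the mean of 3 passages. Adjusted over the list alone, 3 p53 targets and 1 chaperone gene rose. The risen members were Fas, a death receptor (0.77, adjusted p = 0.0261), and Herpud1, a component of endoplasmic reticulum protein degradation. The mean of its kept probes gave 0.37 for Fas (adjusted p = 0.0644). Without the adherent array of experiment 2 the mean fold change was 0.19 for the p53 targets (adjusted p = 0.13) and 0.13 for the chaperones (adjusted p = 0.47). Without that of experiment 1 the chaperones had 0.35 (adjusted p = 0.00278). The chaperone list also lost its call without the adherent array of experiment 3 (adjusted p = 0.0708), the P1 arrays of experiments 2 and 3 (0.0564 and 0.0545), the P2 arrays of experiments 1 and 2 (0.051 and 0.0627) or the P3 array of experiment 3 (0.0667). With median scaling its adjusted p was 0.0814 and with the deposited log2 values 0.0718. With the 75th percentile filter neither list passed (adjusted p = 0.0645 and 0.0805).

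The hypoxia and glycolysis list was lower in mammospheres, by a mean fold change of -0.52 over 24 genes (adjusted p = 2.44e-05, and adjusted p = 0.329 with an estimated correlation). Of its genes 0 rose and 5 fell, or 1 and 9 adjusted over the list alone. Its mean was 10.58 ± 0.19 in adherent cells, 9.98 ± 0.07 in P1, 10.17 ± 0.27 in P2 and 10.05 ± 0.03 in P3 (SD), below every adherent array on 8 of 9 mammosphere arrays. Ndrg1 and P4ha2 had the largest falls. The list of SRF and YAP targets was lower, at -0.83 over 23 genes (adjusted p = 2.00e-05, and adjusted p = 0.329 with an estimated correlation). It had 0 genes risen and 4 fallen, and the same counts adjusted over the list alone. Its genes respond to cell tension and attachment, and SRF is the serum response factor. Serum, attachment and the added growth factors, insulin and albumin changed together in these comparisons. The fall of this list therefore cannot be assigned to any of them. Without the adherent array of experiment 1, where this list stood at 10.94 against 9.73 and 9.54 on the other adherent arrays, the mean fold change was -0.40 (adjusted p = 0.00799). Ccn2, a relative of Ccn1, had the largest fall of the list, -4.45 (SE 0.73, adjusted p = 0.00773), and -3.13 without that array. Its other kept probe, near the floor at 7.25 in adherent cells, had -0.30, and the mean of both -2.37.

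The MHC class I presentation list was lower, at -0.68 over 18 genes (adjusted p = 1.77e-06, and adjusted p = 0.329 with an estimated correlation). As written down, the list also held the class II genes Cd74, H2-Aa and H2-Ab1. Of its genes 0 rose and 5 fell, or 0 and 11 adjusted over the list alone. Its mean was 10.14 ± 0.46 in adherent cells, 9.36 ± 0.10 in P1, 9.56 ± 0.06 in P2 and 9.49 ± 0.14 in P3 (SD), below every adherent array on 9 of 9 mammosphere arrays. The largest falls were those of Psmb8, an immunoproteasome subunit, with -2.38 (SE 0.56, adjusted p = 0.0338), and of Cd74, the MHC class II invariant chain, with -0.96 (SE 0.22, adjusted p = 0.0335). In the 3 passages Cd74 stood between 7.056 and 7.135, near the floor. The list had -0.93 without the adherent array of experiment 2, and also passed there with an estimated correlation (adjusted p = 0.0449). It had -0.49 without the adherent array of experiment 1 (adjusted p = 0.00236), and Psmb8 had -1.54 (adjusted p = 0.0565), and without that of experiment 3 Cd74 had -0.55 (adjusted p = 0.0569).

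**Figure D3:**
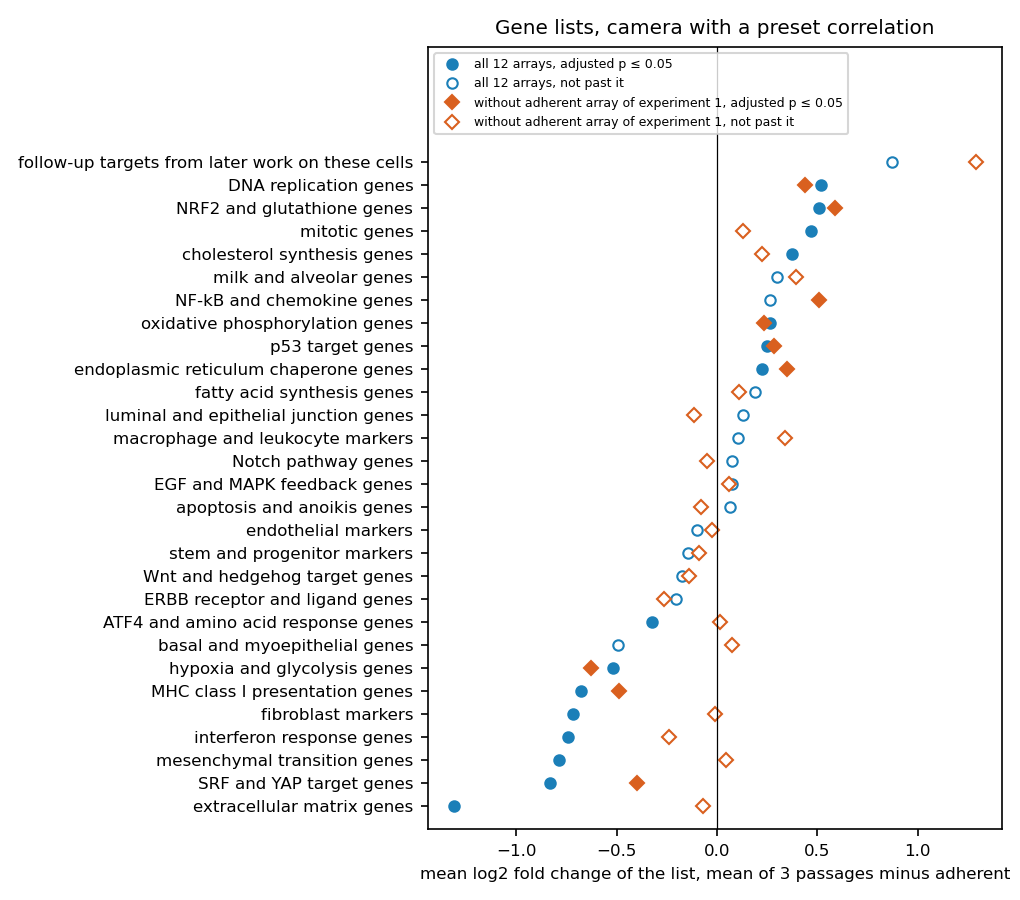
Mean log2 fold change (horizontal axis, mean of 3 passages minus adherent) of each of 29 gene lists (vertical axis); circles are all 12 arrays and diamonds the 11 arrays without the adherent array of experiment 1, filled where camera with the preset correlation gave an adjusted p of at most 0.05. The extracellular matrix list lies at -1.31 with all arrays and at -0.07 without that array, and the NRF2 and glutathione list at 0.51 and 0.59.

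A further 7 of the 15 lists were called for the mean of 3 passages with all 12 arrays and not without the adherent array of experiment 1. The extracellular matrix list had a mean fold change of -1.31 over 24 genes (adjusted p = 0.000229, and 0.614 without that array), the mesenchymal transition list -0.79 over 22 genes (0.00568 and 0.715) and the fibroblast markers -0.72 over 11 genes (0.0215 and 0.909). For these 3 lists the adjusted p was 0.469 with an estimated correlation. The list means on that array were 12.08, 10.67 and 9.04, against 8.32, 8.25 and 6.84 on the adherent array of experiment 2. Without that array the mean of the mesenchymal list was 0.04 while its test still pointed down. Leaving out another adherent array gave larger falls, -1.24 for the mesenchymal list without that of experiment 3 and -1.11 for the fibroblast markers without that of experiment 2. With the deposited log2 values the fibroblast markers had an adjusted p of 0.0505, and in P1 alone 0.0593. Of the mesenchymal genes Tgfbr2, a receptor for TGF-beta, rose by 1.18 (adjusted p = 0.00773) and the transcription factor Snai1 fell by 1.04 (adjusted p = 0.00429), and both had an adjusted p of at most 0.05 also without the array of experiment 1. With median scaling their adjusted p was 0.0911 and 0.078, and the mean of its kept probes gave 0.42 for Tgfbr2 (adjusted p = 0.0834) and -0.68 for Snai1 (adjusted p = 0.00601). Of the matrix genes and the fibroblast markers, 0 rose and 0 fell, over all probes and adjusted over the list alone. The members with the smallest p were Hspg2 (-2.45, adjusted p = 0.0558), Lamc1 (-0.84, adjusted p = 0.0746), Fbln1 (-0.93, adjusted p = 0.175) and Mfap5 (-1.26, adjusted p = 0.23). Hspg2, a basement membrane proteoglycan, passed without the adherent array of experiment 1 at a smaller fold change (-1.14, adjusted p = 0.00208) and without that of experiment 2 (-3.13, adjusted p = 0.0388). It also passed with the experiment number as a block (adjusted p = 0.0486), after normexp (0.0397) and with the 75th percentile filter (0.028). Lamc1 passed without the adherent array of experiment 2 (-1.11, adjusted p = 0.0417) and with the 75th percentile filter (adjusted p = 0.0468). Without the adherent array of experiment 1, Lamc1 had -0.55, Fbln1 -0.21 and Mfap5 -0.13. Of the mesenchymal genes 1 rose and 1 fell, or 1 and 5 adjusted over the list alone.

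The interferon response list had -0.74 over 25 genes (adjusted p = 2.44e-05, and 0.156 without the adherent array of experiment 1), with 0 genes risen and 2 fallen, or 0 and 5 adjusted over the list alone. The fallen members were the transcription factor Irf1 and the ADP-ribosyltransferase Parp14, for which the mean of its kept probes gave -0.70 (adjusted p = 0.0609). The list of ATF4 and amino acid response genes had -0.32 over 27 genes (adjusted p = 0.0184, and 0.855 without that array), with 1 risen and 1 fallen, or 1 and 2 adjusted over the list alone. Without that array its mean fold change was 0.01 while its test still pointed down. It also lost its call without the experiment 3 array of P2 (adjusted p = 0.0506) or of P3 (adjusted p = 0.0525), and in P3 alone it did not pass (-0.13, adjusted p = 0.236). Its members that moved were Slc7a11 and the transcription factor Cebpg, which fell by 0.70 (SE 0.11, adjusted p = 0.00551, and 0.195 with median scaling) and had -0.41 as the mean of its kept probes. The cholesterol synthesis list had 0.38 over 18 genes (adjusted p = 0.00568, and 0.212 without the adherent array of experiment 1), with 4 risen and 0 fallen, or 6 and 0 adjusted over the list alone. Squalene epoxidase, Sqle, rose by 0.97 (SE 0.14, adjusted p = 0.00465), and Cyp51 by 0.95 (adjusted p = 0.0194). The other kept probe of Sqle had 0.38, and the mean of both 0.68, which did not pass (adjusted p = 0.0599). The cholesterol list did not pass in P3 (0.27, adjusted p = 0.103). The mitotic list had 0.47 over 19 genes (adjusted p = 0.0061, and 0.521 without that array), with 0 risen and 0 fallen on either adjustment. Its smallest p were those of Kif23 (1.09, adjusted p = 0.0719), whose other probes gave values of both signs, and Cdca3 (1.01, adjusted p = 0.15). Kif23 passed without the adherent array of experiment 2 (1.53, adjusted p = 0.0192), without the P2 array of experiment 2 (1.19, adjusted p = 0.048) and with the 75th percentile filter (adjusted p = 0.0418), while the mean of its kept probes gave -0.03 (adjusted p = 0.94). Kif23 had 0.65 (adjusted p = 0.186) and Cdca3 0.46 (adjusted p = 0.431) without the adherent array of experiment 1. The mitotic list was higher in P1 by 1.01 (adjusted p = 1.87e-07, and adjusted p = 0.382 with an estimated correlation), and had 0.05 in P2 (adjusted p = 0.964) and 0.34 in P3 (adjusted p = 0.103). On the P2 array of experiment 2 this list stood at 9.02, against 9.93 and 9.95 on the other P2 arrays. Without the adherent array of experiment 1 the mean fold changes were -0.24 for the interferon, 0.23 for the cholesterol and 0.13 for the mitotic list. In P1 these 3 lists still passed without it, with -0.51 (adjusted p = 0.00322), 0.40 (adjusted p = 0.0126) and 0.68 (adjusted p = 0.000104), and in P2 and P3 none did. With an estimated correlation their adjusted p in P1 was then 0.598, 0.508 and 0.508. Without that of experiment 2 they were -1.19, 0.56 and 0.75, and -0.56 for the ATF4 list. With an estimated correlation the adjusted p was 0.469 for the interferon and cholesterol lists and 0.486 for the ATF4 and mitotic lists.

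The other 14 lists did not pass camera for the mean of 3 passages with all 12 arrays. The stem and progenitor markers had a mean fold change of -0.14 over 16 genes (adjusted p = 0.339), with 0 risen and 1 fallen, the progenitor transcription factor Sox9 (-1.35, SE 0.28, adjusted p = 0.0199, and 0.0554 without the adherent array of experiment 2). The luminal and epithelial junction list had 0.13 over 25 genes (adjusted p = 0.339, and 0.0202 without the adherent array of experiment 3, where it was 0.5 with an estimated correlation), with 1 risen, the tetraspanin Cd9 (0.86, adjusted p = 0.0198, 0.108 with median scaling, and 0.58 in place of 0.86 without the adherent array of experiment 1), and 0 fallen. The basal and myoepithelial list had -0.49 over 14 genes (adjusted p = 0.211, and 0.0222 without the adherent array of experiment 2, where it was 0.328 with an estimated correlation), with 0 risen and 0 fallen. Leaving out the adherent array of experiment 1 turned the direction of both, to -0.12 for the luminal list (adjusted p = 0.379) and 0.07 for the basal list (adjusted p = 0.767). Its smallest p were those of Mylk (-1.15, adjusted p = 0.114, and -0.44 without the adherent array of experiment 1) and Col17a1 (0.24, adjusted p = 0.153). The counts of these 3 lists were the same adjusted over the list alone. The milk and alveolar list had 0.30 over 15 genes (adjusted p = 0.384), with Wfdc18 risen and Muc1 fallen, and 2 risen and 1 fallen adjusted over the list alone. The fatty acid synthesis list had 0.19 over 18 genes (adjusted p = 0.222), with the elongase Elovl6 risen (1.57, adjusted p = 0.0209) and 0 fallen on either adjustment. In P1 alone this list passed, with 0.35 (adjusted p = 0.0164, and 0.382 with an estimated correlation).

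Among signalling lists, the EGF and MAPK feedback genes had 0.07 over 21 genes (adjusted p = 0.381), with 4 risen and 2 fallen, or 6 and 3 adjusted over the list alone. The urokinase receptor Plaur rose by 1.33 (SE 0.19, adjusted p = 0.00396) and the inhibitor Spry4 by 1.11 (adjusted p = 0.0114), while Dusp5 and the EGF family ligand Hbegf (-1.04, adjusted p = 0.0131) fell. The ERBB receptor and ligand list had -0.20 over 11 genes (adjusted p = 0.361), with 1 risen and 2 fallen on either adjustment: the ligand Btc rose, and Hbegf and the feedback inhibitor Errfi1 fell. The labels name added EGF for mammospheres only, so its part in these 2 lists cannot be told apart from that of serum or attachment. The NF-kB and chemokine list had 0.27 over 24 genes (adjusted p = 0.222, and 0.0194 without the adherent array of experiment 1, where it was 0.521 with an estimated correlation), with 3 risen and 0 fallen on either adjustment. Cxcl2 was among them, with Csf3, the granulocyte colony-stimulating factor (1.55, SE 0.26, adjusted p = 0.0083, and 0.84 as the mean of its kept probes). The Notch list had 0.08 over 17 genes (adjusted p = 0.826) and the Wnt and hedgehog list -0.17 over 20 genes (adjusted p = 0.361), each with 0 risen and 0 fallen on either adjustment. Their smallest p were those of Hey1 (1.25, adjusted p = 0.147), Rfng (0.26, adjusted p = 0.282), Sfrp1 (-0.72, adjusted p = 0.0897) and Ptch1 (0.76, adjusted p = 0.093). Sfrp1, a secreted Wnt antagonist, passed without the adherent array of experiment 1 (-0.99, adjusted p = 0.0162), and Hey1 had 0.48 without it (adjusted p = 0.41). The apoptosis and anoikis list had 0.07 over 20 genes (adjusted p = 0.806), with 3 risen and 3 fallen on either adjustment. The pro-apoptotic Bid rose by 1.35 (SE 0.23, adjusted p = 0.0088) and Fas by 0.77, and the anti-apoptotic Bcl2 had -0.56 and the kinase Dapk1 -0.68. The mean of its kept probes gave 0.83 for Bid (adjusted p = 0.0111), -0.45 for Bcl2 (adjusted p = 0.0603) and -0.20 for Dapk1 (adjusted p = 0.303). Leaving out the adherent array of experiment 1 turned the direction of the Notch list (-0.05, adjusted p = 0.603) and of the apoptosis list (-0.08, adjusted p = 0.603).

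Markers of other cell types were also listed. The macrophage and leukocyte markers had a mean fold change of 0.10 and a median of -0.02 over 8 genes, and camera gave a downward direction (adjusted p = 0.426), so that mean and test differ in sign. The mean was 0.34 without the adherent array of experiment 1 and -0.04 without that of experiment 2. The list passed camera without none of the arrays (smallest adjusted p = 0.338). Its smallest p were those of Cd52 (-0.30, adjusted p = 0.0817) and Itgam (-0.26, adjusted p = 0.175). The endothelial markers had -0.10 over 7 genes (adjusted p = 0.438), the smallest p being those of Eng (-0.43, adjusted p = 0.138) and Flt1 (0.44, adjusted p = 0.247), which had -0.18 and 0.18 without the adherent array of experiment 1. In both lists 0 genes rose and 0 fell on either adjustment.

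Later work on these cells followed up Slc7a11, the innate immune receptor Tlr2, the teneurin Tenm4 and Erbb2. Those genes may have been picked from these arrays, so their list is not independent evidence of a direction. The list had 0.87 over 4 genes, with 2 risen and 0 fallen on either adjustment. Its adjusted p was 0.331 by camera, 0.041 by fry and 0.0813 by fry with the experiment number as a block. Tlr2 rose by 1.23 (SE 0.18, adjusted p = 0.00436), from 8.37 ± 0.38 in adherent cells to 9.52 ± 0.23 in P1, 9.41 ± 0.02 in P2 and 9.88 ± 0.38 in P3 (SD, n = 3), and its adjusted p was 0.0722 with median scaling. Tenm4 had -0.68 (SE 0.44, adjusted p = 0.407), and 0.18 without the adherent array of experiment 1 (adjusted p = 0.468). Erbb2, read by a mouse probe that cannot be assigned to the rat transgene or the mouse gene, had -0.30 (SE 0.15, adjusted p = 0.276), -0.47 without the adherent array of experiment 1 (adjusted p = 0.0802) and -0.11 without that of experiment 3 (adjusted p = 0.758).

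Commonly used stem cell markers were not called. Cd44, the hyaluronan receptor, stood at 11.87 ± 0.39 in adherent cells and 11.93 ± 0.27 in P1 (SD, n = 3), with a mean fold change of -0.08 (SE 0.21, adjusted p = 0.881). Cd24a (-0.06, adjusted p = 0.825), Prom1 (-0.03, adjusted p = 0.888), Sox2 (0.01, adjusted p = 0.986) and Pou5f1 (-0.29, adjusted p = 0.211) had adherent levels between 7.00 and 7.41, near the floor, where a difference may not be detectable. Ly6a, Aldh1a1 and Nanog had no probe above the filter. Of the keratins, Krt8 had 0.52 (adjusted p = 0.36), Krt18 0.01 (adjusted p = 0.993) and Krt14 -0.15 (adjusted p = 0.894), and without the adherent array of experiment 1 they had 0.21, -0.46 and 0.66. E-cadherin, Cdh1, had -0.26 (adjusted p = 0.375, and 0.0411 without the adherent array of experiment 1), and for Pou5f1 the latter was 0.0152. With all 12 arrays the other kept probe of Cdh1 had 0.18, and the mean of both -0.04 (adjusted p = 0.881). Vimentin, Vim, had -2.03 (SE 0.58, adjusted p = 0.0686), with an adherent SD of 1.97, and -0.99 without that array (adjusted p = 0.0895). It passed without the adherent array of experiment 3 (-2.95, adjusted p = 0.0133) and with the 75th percentile filter (adjusted p = 0.0361).

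Of the 83 genes named by the rule, 55 had an adjusted p of at most 0.05 for the mean of 3 passages, and 17 of these lost it without at least 1 array. Bcl2 (adjusted p = 0.0454) lost it without 10 of the 12 arrays in turn, Errfi1 (0.049) without 11, Parp14 (0.0437) without 10, Psmb8 (0.0338) without 9, Cox5a (0.0329) without 8, Btc (0.0315) and Cd74 (0.0335) without 7 and Dapk1 (0.0383) without 6. The highest adjusted p of these genes over the arrays left out ranged from 0.0626 for Cd74 to 0.159 for Dapk1. Irf1 had 0.0669 and 0.0979 without the adherent arrays of experiments 2 and 3, Hbegf 0.051 and 0.0576, and Herpud1 0.0621 and 0.0825. Cyp51 (0.0944), Elovl6 (0.101) and Fas (0.0999) lost it without the adherent array of experiment 3 alone, as did Fen1, and Slc7a11 and Sox9 as given above. Among those lost without the adherent array of experiment 1 were Btc (0.0793), Errfi1 (0.121) and Parp14 (0.0659). With median scaling, 21 of the 83 genes lost it.

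Against adherent cells, 301 probes were called in P1 (146 higher, 155 lower), 171 in P2 (70 higher, 101 lower) and 186 in P3 (86 higher, 100 lower). The mean of the 3 passages gave 305 (118 higher, 187 lower). In at least 1 passage 392 were called (198 higher, 194 lower), and the series' design text gives 495 transcripts for such a union at the same thresholds. In all 3 passages 96 were called in 1 direction (35 higher, 61 lower). Without the adherent array of experiment 1 the counts were 569, 417, 456 and 507 probes, 787 in at least 1 passage and 248 in all 3. Of the 392 probes, 348 were among the 787. Without the adherent array of experiment 3 they were 148, 112, 122 and 194 probes, 212 in at least 1 passage and 64 in all 3. Single mammosphere arrays mattered as well: without its own arrays of experiments 1 and 2 in turn, P1 had 97 and 153 probes, P2 51 and 91, and P3 57 and 77. The union was then 214 and 234 without those of P1, and the count in all 3 passages 54 and 59 without those of P1, 37 and 63 without those of P2, 38 and 51 without those of P3, and 60 without the P1 array of experiment 3.

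**Figure D4:**
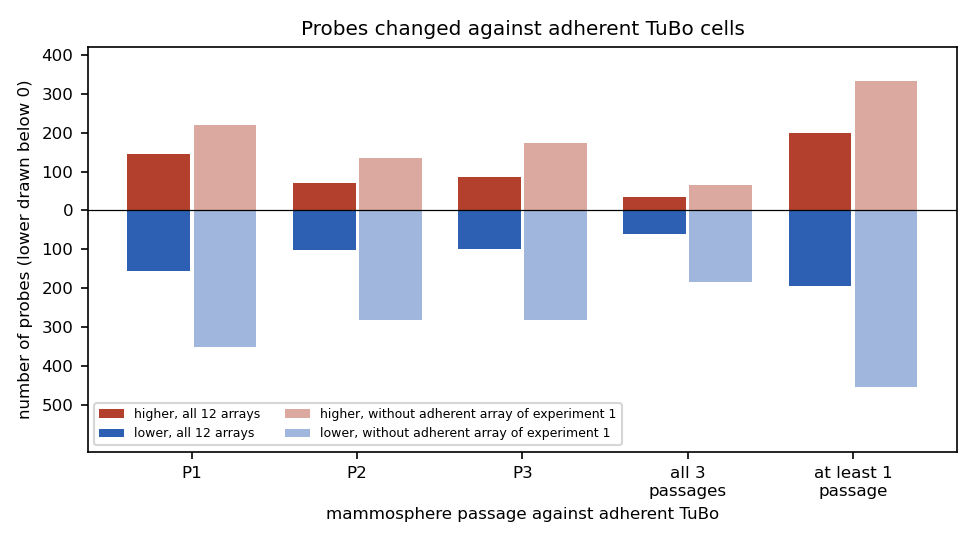
Number of probes called higher (above 0) and lower (below 0) in mammospheres than in adherent TuBo cells, per passage, in all 3 passages and in at least 1 (horizontal axis); dark bars are all 12 arrays and pale bars the 11 arrays without the adherent array of experiment 1. With all arrays 301, 171 and 186 probes were called in P1, P2 and P3, and 569, 417 and 456 without that array.

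The fold changes of the passages against adherent cells were alike in part because the 3 comparisons share their controls. Across probes, which are not independent replicates, r was 0.856 for P1 and P2, 0.848 for P1 and P3 and 0.886 for P2 and P3. Unchanged groups simulated against the same arrays gave 0.757, 0.768 and 0.744. The covariance was 0.136, 0.141 and 0.135, against 0.0611, 0.0611 and 0.061. Fold changes had 1 sign in 78.9%, 77.6% and 79.0% of probes, against 70.2%, 70.2% and 69.6%. P1 and P2 shared 49 higher and 78 lower calls, P1 and P3 50 and 80, and P2 and P3 40 and 65, with 0 in opposite directions. Independent lists would share 0.451, 0.555 and 0.266 higher and 0.691, 0.685 and 0.446 lower, and the simulation 17.5, 17.5 and 17.8 in all. With 3 controls no split leaves enough arrays on each side, so part of the excess may come from the shared controls. The simulation also leaves out that P2 and P3 arrays of 1 experiment number deviated together, so part of what these 2 share may come from that.

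Between passages, limma called 0 probes for P2 against P1, 0 for P3 against P2, 0 for P3 against P1 and 0 for any difference among the 3. At an unadjusted p below 0.05 the counts were 975, 525, 1064 and 846 of 22640 probes. The 0 calls do not exclude large differences of probes with a large spread. Gsta3, for example, was 1.85 higher in P3 than in P2 (SE 0.50) and was not called. Nor was Klk14, with -1.79 for P2 against P1 (SE 0.75). Without the P3 array of experiment 3, the glutathione transferase Gsta1 was higher in P3 than in P2 (1.74, adjusted p = 0.0165) and than in P1 (1.94, adjusted p = 0.00948), with an adjusted p of 0.0204 for any difference. The serine protease Tmprss4 was then also higher in P3 than in P2 (1.5, adjusted p = 0.0165). Both genes were named after their values were seen. Gene lists differed more: camera with the preset correlation gave 9 lists for P2 against P1, 10 for P3 against P2 and 8 for P3 against P1. With an estimated correlation these were 0, 1 and 0. The 1 was the NRF2 and glutathione list, higher in P3 than in P2 by a mean of 0.59 (adjusted p = 1.56e-13, adjusted p = 0.0223 with an estimated correlation, and adjusted p = 0.0274 by fry). With the experiment number as a block the last 2 were 0.0495 and 0.0432. The p53 targets were higher in P2 than in P1 by 0.49 (adjusted p = 6.04e-12, adjusted p = 0.0552 with an estimated correlation, and adjusted p = 0.0378 by fry, or 0.132 by fry with that block). The mitotic and DNA replication lists were lower in P2 than in P1, by -0.96 (adjusted p = 7.80e-19) and -0.79 (adjusted p = 1.49e-28), and with an estimated correlation the adjusted p was 0.181 and 0.156. Both were higher in P3 than in P2, by 0.29 (adjusted p = 0.0101) and 0.20 (adjusted p = 0.0149), and with an estimated correlation the adjusted p was 0.673 and 0.727. These rises hang on the P2 array of experiment 2, at 9.02 and 8.60. The other P2 arrays had 9.93 and 9.95 for the mitotic and 9.36 and 9.40 for the replication list. The P3 arrays had 10.12, 9.97 and 9.69 for the mitotic and 9.47, 9.33 and 9.17 for the replication list.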

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

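Of the tests in this part, the list differences and the splits were planned before the result was seen, and so were the tests of scaling and of single arrays for the DNA replication list, except that normexp was added to the scalings after seeing the data.

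The difference between P3 and P1 mammospheres was tested for each list. By camera with the preset correlation, 8 of the 29 lists differed. The DNA replication genes were lower in P3 by a mean fold change of -0.589 (adjusted p = 1.76e-18), the mitotic genes by -0.673 (adjusted p = 2.66e-10), the cholesterol synthesis genes by -0.288 (adjusted p = 2.53e-05) and the fatty acid synthesis genes by -0.228 (adjusted p = 0.00227). Higher in P3 were the NRF2 and glutathione genes by 0.505 (adjusted p = 1.35e-07), the p53 targets by 0.37 (adjusted p = 2.4e-06), the ATF4 and amino acid response genes by 0.342 (adjusted p = 0.00594) and the interferon response genes by 0.367 (adjusted p = 0.0408). With an estimated correlation, in the same order, the adjusted p was 0.211, 0.363, 0.363, 0.211, 0.149, 0.178, 0.746 and 0.768, and fry gave 0 lists (smallest adjusted p = 0.107). Each difference is therefore open to genes of a list moving together from array to array. Of the 10 splits of the 6 arrays, 1 gave as many lists as the real split, which is the real one with 8, and the highest other gave 6, so the splits are too few for a share under 0.05.

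The DNA replication list mean lay lower on 3 of 3 P3 arrays than on every P1 array, at 9.32 ± 0.15 against 9.91 ± 0.18 (SD, n = 3). Scaling of the arrays was tested as a technical explanation, and the list passed under 3 of 3 other scalings, with mean fold changes of -0.815 with median scaling, -0.579 with the deposited log2 values and -0.627 after normexp, which argues against scaling as the whole cause. It also passed without each of the 6 arrays in turn, a count of 6, so that no single array carries it. Of the 10 splits of the 6 arrays, 1 gave a mean difference as large, the real one at 0.589, and the highest other gave 0.403, too few splits for a share under 0.05. Among the passages the list was lowest in P2 (9.12 ± 0.45), and P3 lay above P2 by 0.202 (adjusted p = 0.0149, and 0.727 with an estimated correlation). This order hangs on the P2 array of experiment 2, at 8.60. The other P2 arrays had 9.36 and 9.40, and the P3 arrays 9.47, 9.33 and 9.17. The order of P2 and P3 is therefore open, and the values neither show nor exclude a steady decline over passages. A higher rate of proliferation in P1, or cultures collected at another density or phase of growth, stays open and was not tested.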

How the results depend on the processing

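The normexp correction and the 75th percentile filter were chosen after seeing the data, the other settings before. Counts are given as P1, P2, P3, at least 1 passage, all 3 passages and the mean of 3 passages against adherent cells, from 301, 171, 186, 392, 96 and 305. Median scaling gave 105, 24, 23, 112, 12 and 148, with 76.2%, 54.2%, 47.8%, 75.9%, 41.7% and 64.2% of them higher, against 48.5%, 40.9%, 46.2%, 50.5%, 36.5% and 38.7%. With it the median fold change of all probes was 0.096 for P1 and for P2 against adherent cells, 0.011 for P3, -0.107 for P3 against P2 and -0.106 for P3 against P1. Array weights gave 468, 386, 317, 703 and 158 for the first 5. Without the fold threshold they were 625, 310, 368, 808, 170 and 1187, because that threshold is dropped. With only the 2 groups compared, which leaves fewer arrays for the spread, they were 108, 4, 42, 132 and 3. The cause was not tested for median scaling and array weights. The deposited log2 values, no filter, the interquartile filter, the trend with a robust prior, normexp and the 75th percentile filter moved each count by less than 1.5 times. Leaving out each array in turn gave 97 to 569, 51 to 417, 57 to 456, 212 to 787, 37 to 248 and 194 to 507, and for the passages 0 to 2 (P3 against P2), 0 to 1 (P3 against P1) and 0 to 1 (any difference). Between passages 0 probes were called in every other setting run.

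The number of lists passing was 15, 0 with an estimated correlation, and 9 to 15 with single arrays left out. Of single lists, 17 calls were lost and 3 gained over the arrays left out, and 20 lost in other settings. Of named genes, 81 calls were lost and 9 gained over the arrays left out, and 28 lost and 6 gained in other settings. No called gene changed sign and no called list the direction of its test. Where neither setting gave a call, the direction differed 7 times for lists and 19 times for genes.

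Over all groups the experiment numbers did not meet the bar for pairing, and for P2 with P3 they did. Of 18 pairs with 1 number, 8 had a correlation of deviations over 0.1 (range -0.109 to 0.424). Of the 12 arrays, 9 correlated best with their own number. Median intensities before normalization also followed the number in P1, P2 and P3. They were 131.9, 135.2 and 132.4 in experiment 1, 139.2, 147.7 and 150.5 in experiment 2, and 104.5, 99.4 and 104.4 in experiment 3. The adherent arrays had 107.8, 112.3 and 116.5. Sharing by number beyond P2 and P3 is therefore not excluded. The labels name the number as an experiment in all 4 groups, and a few probes followed it in every group, as given below. What the arrays of 1 number share is not stated in the labels, and the main fit has no block. With the experiment number as a replicate block the counts were 343, 212, 215, 456, 110 and 337. For P3 against P2 the block changed no call: 0 probes and 10 lists passed. The block was fitted over all 12 arrays, adherent and P1 arrays included, so this is not a test on pairs of P2 and P3 alone. For the mean of 3 passages fry gave 5 lists with the block in place of 7. Against adherent cells it gave 6 in place of 7 for P1, 0 in place of 2 for P2 and 2 in place of 8 for P3. For P2 against P1 it gave 0 in place of 1.

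Of 10 splits of 6 arrays, 1 gave as many probes as the real one for P1 (301, highest other 0), 1 for P2 (171, highest other 0) and 1 for P3 (186, highest other 1), too few splits for a share under 0.05. Of 100 splits of 12 arrays, 1 reached the mean contrast (305, highest other 2), 1 the union (392, highest other 109) and 1 all 3 passages (96, highest other 0). For these 3 counts the share was under 0.05, which argues against chance. The number of lists was reached by 3 splits (15, highest other 17). Another split gave more lists and 0 lists passed with an estimated correlation, so chance stays open for that number. The splits moved all arrays freely, although P2 and P3 were taken as paired. Between passages the real count was 0, which every split reaches (10 of 10 for each pair, highest other 0, and 100 of 100 for any difference, highest other 10), so these splits decide nothing. Detection p filters, neqc and a slide block were not run. Signal near the floor limits fold changes of dim probes.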

Other observations

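The tests of this part, on the adherent array of experiment 1 and on the unnamed probes, were chosen after the results were seen.

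Milk protein and lysozyme transcripts varied between mammosphere arrays of a group. Beta-casein, Csn2, stood at 6.84, 6.87 and 6.66 on the adherent arrays and at 7.22, 7.07 and 7.57 in P1. In P2 it reached 14.18, 12.13 and 9.92, and in P3 9.70, 8.55 and 12.52. Kappa-casein, Csn3, stood between 15.17 and 15.62 on all 12 arrays, and whey acidic protein, Wap, between 6.52 and 6.89. Lysozyme, Lyz2, a transcript typical of macrophages and also of some epithelia, was at 11, 10.07 and 11.82 in P3. It was at 13.62 on the P2 array of experiment 3, 11.05 on the P1 array of experiment 3, 12.38 on the adherent array of experiment 1, and 6.61 and 6.65 on the other adherent arrays. Lyz1 followed it, with 10.53, 9.94 and 10.33 in P3. The leukocyte markers Ptprc, Adgre1 and Tyrobp stayed between 6.52 and 7.17 on all 12 arrays. Csf1r lay between 6.89 and 7.53, with its highest values, 7.53 and 7.43, on the adherent arrays of experiments 2 and 3. These genes were chosen after their values were seen, and no test was made.

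On the adherent array of experiment 1, the matrix list had a median of 4.29 above the other 2 adherent arrays, the mesenchymal list 1.93, the interferon list 1.48, the ATF4 list 1.12 and the mitotic list -1.15. Between-array normalization is argued against by a median of 4.26 for the matrix list in unnormalized intensities. The highest matrix median among the 9 mammosphere arrays was 0.0765, so none of them had this pattern. A swap with a mammosphere array would leave the high array among the adherent ones. That value therefore cannot decide on a swap. Fibroblasts in the culture could be a source: 8 of 15 fibroblast markers with a probe were at least 1 log2 higher there, and 0 had a level over 8 on the other 11 arrays, but the count fell between the bounds set for and against. Of the 16 listed markers 5 stand on another list. Col1a1 had 11.98 there and a mean of 6.81 on the other 11 arrays, Col1a2 8.57 against 6.96 and Dcn 9.65 against 6.77. Col3a1 (7.35 against 6.81) and Lum (7.05 against 6.84) had probes near the floor on every array. The sizes of these differences are not compared between probes. With the count undecided, fibroblasts cannot be told apart from TuBo cells in a mesenchymal state or another culture. Other transcripts were low there, among them 86 bright probes that were picked for a large fall (median -2.33). Dilution by other cells was tested on the bright luminal and junction genes, which had a median of -0.848 (quartiles -1.17 and -0.621). This fell between the bounds set for and against. The 86 probes had quartiles of -2.67 and -2.15. A single dilution would lower both sets alike, unless the other cells express the luminal genes. These values therefore argue against it as the whole cause for the 86 probes. As a part of their fall, dilution stays open.

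A set of probes with no gene symbol was dim on the arrays of experiment 1. In adherent cells, P1 and P2 the 6 probes had values between 6.58 and 7.21 on those arrays, and on the arrays of experiments 2 and 3 between 7.74 and 13.45. In P3 the experiment 1 array was between 7.30 and 11.29. Between-array normalization is argued against by a median difference of 2.03 in unnormalized intensities. A general difference of the experiment 1 arrays could not be decided: apart from these 6 probes, 1 probe was set apart in every group by experiment 1, and 3 each by experiments 2 and 3, too few to compare. Of the 6 probes 4 were also higher in experiment 3 than in the other experiments, by over 0.5 log2 in every group. A transcript or variant carried by the cells of some experiments stays open and was not tested.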
